A study of Homo sapiens with 6 samples.

How the data were processed

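RNA from 6 libraries of U2OS cells was sequenced from total RNA, with libraries made with a TruSeq RNA kit per the labels' protocols. The authors deposited a table of raw read counts per gene and a table of FPKM values per gene, with 1 column for each of the 6 libraries, and all columns were matched to a library by name (0 columns were left unmatched). Per the submitters' processing notes the genome build was hg38. The aligner, the counter, the annotation release and the strand setting are not given in the sources used here. The deposited counts are whole numbers and were not normalized. The deposited FPKM values have a length model and tool not given in the sources used here, and 89.8% of the values of 12316 genes lay within 5% of a fixed ratio per gene to the count share of the library.

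The count table had 50550 rows, of which 44494 carried a gene symbol and 6056 no gene symbol, holding 3.22 to 4.26% of counts per library. Those rows stayed in library sizes and tests but are not named. Of the rows with symbols, 41993 matched a RefSeq table of GRCh38.p14, 438 of them through an older symbol, and 5061 were numbered copies of a gene. Coordinates come from that table and are 1-based. Total counts ranged from 61815841 to 87227980 per library. Intervals on counts cover counting error only.

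Libraries were grouped by their titles, and the only comparison the labels give is Lv_LINC00673 (n = 3) against Lv_NC (n = 3). Groups, tests, gene lists, the rule for named genes and the alternatives first listed below were fixed before the data were examined. Counts were filtered with filterByExpr, scaled by TMM and tested with edgeR 4.0.16's quasi-likelihood test (estimateDisp and glmQLFit with robust settings, glmQLFTest, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over 21933 genes. Every adjusted p for a gene is from that test unless another is named. The threshold was an adjusted p of 0.05, with a second count at a fold of 2. SE is the log2 fold change divided by the square root of the F statistic, and intervals are at 95%. Levels are TMM-normalized CPM, given as mean ± SD.

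The rule for named genes took LINC00673, the 10 highest and 10 lowest log2 fold changes among genes past the threshold with a mean of at least 1 CPM and no overlap between groups, the 5 higher and 5 lower genes of smallest p not yet named, and up to 4 members of each list with the largest change past the threshold. Rows without a symbol were skipped, and 155 genes besides LINC00673 were chosen. Part of these are described in the text, and a few are not reported here. Names such as SOX9, RPL38, and those in the closing section on gene families, were chosen after their values were seen. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), with Benjamini-Hochberg adjustment over the 35 lists with at least 5 tested members, out of 36 fixed. None of the 10 calls held with an estimated correlation. For the NF-kappaB, ATF4 and cholesterol lists the estimate was -0.011, 0.0046 and 0.0054, under the preset value. Correlation between members alone therefore does not account for the loss of these calls. The form with an estimated correlation also uses only the residual degrees of freedom of the libraries, while the preset form uses those of all genes. Its adjusted p-values below therefore do not measure correlation between members alone. The fry test, which asks whether a list's genes move on balance one way and does not compare them with other genes, called 14 lists, including those 10. The others were the p53 target, YAP/TEAD target, extracellular matrix and chondrocyte lists (fry adjusted p = 0.0022, 0.0022, 0.0082 and 0.0072).

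The lists were S-phase and DNA replication, G2/M and mitosis, p53 target, interferon-stimulated, ERK output, immediate early and heat shock, NF-kappaB and inflammatory, extracellular matrix, matrix protease and inhibitor, epithelial-mesenchymal transition and adhesion, osteoblast and bone, chondrocyte, TGF-beta target, YAP/TEAD target, Wnt target, hypoxia, glycolysis, cholesterol synthesis, fatty acid synthesis and desaturation, unfolded protein response, ATF4 and amino acid stress, oxidative stress, nuclear-encoded respiratory chain, mitochondrially encoded, cytosolic ribosomal protein, replication-dependent histone, nuclear noncoding RNA, apoptosis, lysosome and autophagy, genes tied to LINC00673 in other tumour types, neighbours of LINC00673, blood and immune, endothelial, epithelial, neural and muscle, and housekeeping genes.

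Genes within 2 Mb of LINC00673 were compared with all other tested genes by Fisher's exact test. Chromosome medians were compared with 10000 random sets of the same size matched on expression in 10 bins, adjusted over 23 chromosomes. Alternatives were DESeq2 1.42.0, RLE and upper-quartile factors, library totals, no filter, a filter of at least 1 CPM in 3 libraries, limma-voom, non-robust fits, a replicate block, limma on log2(FPKM + 1) and log2(FPKM + 0.1), and leaving out each library. The FPKM fold changes are on the log2(value + pseudocount) scale, which understates changes of low genes. After the data were seen, further alternatives were added: a GC and length offset per library, fitted with smooth terms in mgcv 1.9.3 to genes above a mean log2 CPM of 2, the same genes without it, the offset with the replicate block, summed copies, libraries thinned to the smallest total, and the fit without the first library of each group. GC content came from the longest GENCODE transcript of each gene and length from the ratio of count to FPKM, and 84.0% of tested genes and 93.2% of called genes had both values.

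The scripts were tested on simulated counts drawn from the means and sizes of these libraries. For Lv_LINC00673 against Lv_NC, run on 21273 genes, 14.9% of genes changed by a fold of 1.5, 70.1% changed by a fold of 2 and 97.0% changed by a fold of 4 were recovered, and 11 of 132 calls were false. Only 67, 67 and 66 genes were changed at these folds, a much smaller share than passed in the data. Recovery after adjustment depends on that share, so these percentages do not give the recovery in the data. In the simulated lists 1 of 1 changed list and 1 of 20 unchanged lists were called. On 18423 genes with a simulated GC and length trend and no change, calls went from 2118 to 0 with the offset. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 were used for tables and figures.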

Results

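The series measured RNA by sequencing in U2OS, an established human osteosarcoma cell line. It holds 6 libraries, 3 titled Lv_LINC00673 and 3 titled Lv_NC, and its title names depletion of LINC00673, a long noncoding RNA, as the subject. The titles do not say what NC stands for, and the design text names wild-type cells, so Lv_NC may not be a vector control. In that case the fold changes would include any effect of the vector itself. Lv_NC is used here as the reference group, and every fold change is Lv_LINC00673 over Lv_NC. Total counts were 71237493, 61815841 and 63937475 in Lv_LINC00673 libraries 1 to 3 and 81148605, 87227980 and 76814723 in Lv_NC libraries 1 to 3. Nothing in the labels says that the libraries of a group came from separate cultures, so the p-values below measure only the spread between these libraries, which may be technical.

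The first question was whether LINC00673 itself differed between the groups. LINC00673 lies on chromosome 17 from 72403322 to 72592804 (GRCh38) and is annotated as a long noncoding RNA. Its level was 6.39 ± 0.159 TMM-normalized CPM (SD, n = 3) in Lv_LINC00673 and 8.50 ± 1.24 (SD, n = 3) in Lv_NC. Its counts were 479, 417 and 435 against 709, 751 and 516, and the deposited FPKM values were 2.82, 2.73 and 2.80 against 3.53, 3.46 and 2.75, which overlap. The fitted level in Lv_LINC00673 was 75.1% of that in Lv_NC (95% interval 58.1 to 97.0%; log2 fold change -0.41, SE 0.16). The unadjusted p was 0.0324 and the adjusted p of edgeR's quasi-likelihood test was 0.0924, so the difference did not pass the threshold of 0.05, although all 3 Lv_LINC00673 libraries lay below all 3 Lv_NC libraries in CPM. With the GC and length offset described below the log2 fold change was -0.10 (adjusted p = 0.638; range over 24 alternatives 0.0528 to 0.714). The lower bound of the interval excludes a level below 58.1% in these libraries. Because the target did not pass the test, the groups are named by their library titles throughout, and directions are those between the libraries labelled Lv_LINC00673 and Lv_NC.

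**Figure D1:**
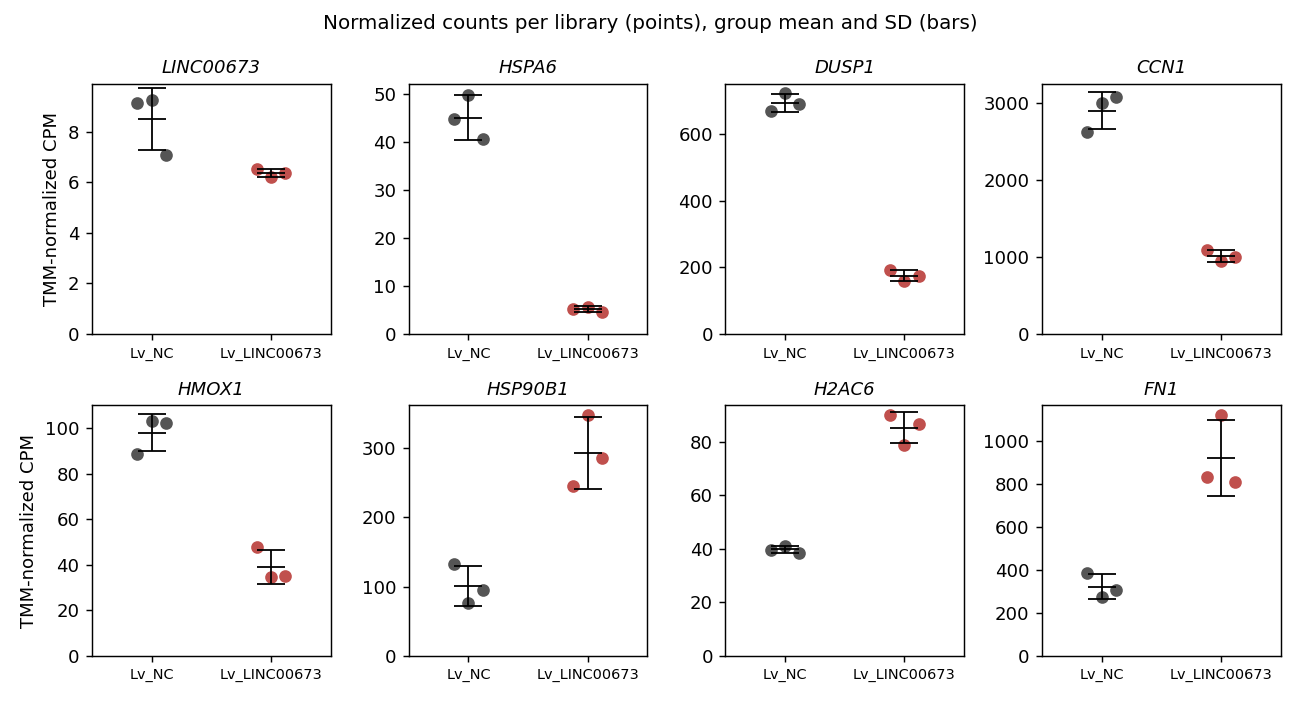
TMM-normalized CPM of 8 genes in each library (points) with the group mean and SD (bars, n = 3), each panel on its own linear axis from 0. LINC00673 lay at 6.39 ± 0.159 against 8.50 ± 1.24 CPM, while HSPA6, DUSP1, CCN1 and HMOX1 were lower and HSP90B1, H2AC6 and FN1 higher in the libraries labelled Lv_LINC00673.

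The main comparison asked which genes differed between the groups. The stress-inducible chaperone gene HSPA6 fell from 45 ± 4.63 CPM in Lv_NC to 5.19 ± 0.555 CPM in Lv_LINC00673, lower in 3 of 3 libraries (SD, n = 3; 8.67-fold, log2 fold change -3.12, SE 0.14, adjusted p = 6.85e-05). DUSP1, which encodes a phosphatase that switches off MAP kinases, fell from 694 ± 27.5 to 175 ± 16.2 CPM (log2 fold change -1.99, SE 0.09). CCN1, a secreted matrix protein gene induced by growth factors, fell from 2903 ± 242 to 1012 ± 74.2 CPM, and the smooth muscle actin-binding gene TAGLN from 123 ± 3.24 to 50.1 ± 5.31 CPM. In the other direction the core histone gene H2AC6 rose from 39.7 ± 1.25 to 85.2 ± 5.71 CPM, the carbonic anhydrase gene CA9 from 64.1 ± 0.945 to 127 ± 7.21 CPM, the acetyltransferase gene EP300 from 29.3 ± 2.25 to 69.6 ± 6.52 CPM and the Mediator subunit gene MED14 from 5.98 ± 0.745 to 20 ± 2.41 CPM. With the GC and length offset described below the log2 fold change of MED14 went from 1.74 to 1.06.

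Of 21933 genes tested, 5883 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 3145 higher and 2738 lower in Lv_LINC00673. By at least 2-fold, 1837 passed, 1657 of them higher and 180 lower. With library totals alone these were 2292 higher and 111 lower. The libraries of the groups did not overlap at 9889 tested genes (45.1%), where chance gives 10%. Scaling by library totals alone moved the median log2 fold change of all tested genes by 0.17 and gave 76.8% of calls as higher, against 53.5% with TMM factors and 66.7% for the deposited FPKM values on the log2(FPKM + 1) scale. Leaving out 1 library lowered the count to 2716 without Lv_LINC00673 library 2, 2830 without Lv_LINC00673 library 3, 3631 without Lv_NC library 2 and 2913 without Lv_NC library 3. It was 6490 without Lv_LINC00673 library 1 and 5613 without Lv_NC library 1.

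Fold changes followed the GC content and length of the genes. Over 11890 genes above a mean log2 CPM of 2, the Spearman correlation across genes, which are not independent replicates, was -0.50 between log2 fold change and GC content and 0.48 between log2 fold change and length. The decile of genes with the lowest GC content had a median log2 fold change of 0.56 and the highest decile -0.25. The shortest decile had -0.35 and the longest 0.54. A fit with a GC and length offset for each library, chosen after the data were seen and run on 18423 genes, called 5043 genes, 2766 higher and 2277 lower, of which 3104 were also called without it. By at least 2-fold it called 744, 610 higher and 134 lower. On the same 18423 genes without the offset 5716 passed, 1613 of them by at least 2-fold, 1479 higher and 134 lower. Its values are given below beside each gene group as the offset values.

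**Figure D2:**
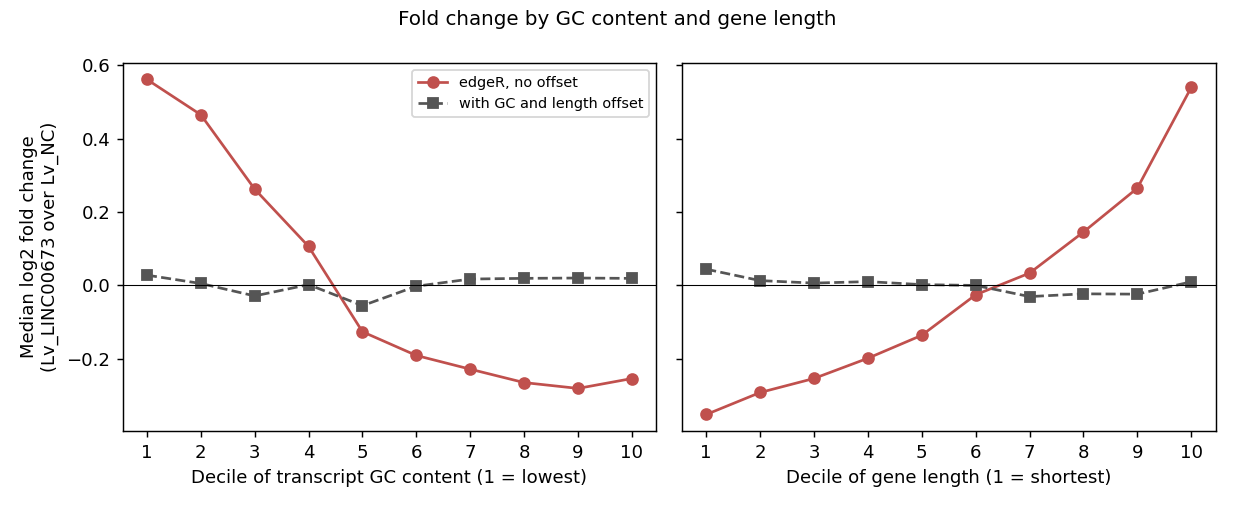
Median log2 fold change (Lv_LINC00673 over Lv_NC) of genes by decile of transcript GC content (left) and of gene length (right), without an offset (red circles) and with the GC and length offset (grey squares). Without the offset, medians ran from 0.56 at the lowest to -0.25 at the highest GC content and from -0.35 at the shortest to 0.54 at the longest genes.

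The named genes with the highest fold changes were mostly of low level in Lv_NC. IFT80, an intraflagellar transport gene on chromosome 3, had counts of 361, 562 and 466 in Lv_LINC00673 against 26, 0 and 0 in Lv_NC (log2 fold change 5.88, SE 1.06, adjusted p = 0.0119). The counting rules are not given in the sources used here, so whether IFT80 reads were assigned alike in both groups is uncertain. MFSD2B, a sphingolipid transporter gene, had counts of 779, 70 and 530 against 26, 37 and 24, so its level varied widely among the Lv_LINC00673 libraries. The centrosomal gene CEP162 rose from 0.269 ± 0.186 to 2.06 ± 0.505 CPM, the giant muscle protein gene TTN from 0.334 ± 0.0632 to 1.89 ± 0.605 CPM, ARHGAP28 from 0.309 ± 0.315 to 1.91 ± 0.665 CPM, SHOC1 from 0.381 ± 0.0988 to 2.01 ± 0.592 CPM and the Wnt ligand gene WNT2B from 0.844 ± 0.0586 to 4.34 ± 2.63 CPM. The lncRNA LOC105379271 rose with a log2 fold change of 2.96. HMGA2-AS1, antisense to HMGA2, and POTEJ, a member of a family of near-identical genes, had log2 fold changes of 2.68 and 2.45 and are uncertain, since reads of the partner or copies cannot be told apart without the strand and counting rules. The smallest p-values also included the histone gene H4C15 (log2 fold change 1.05, SE 0.10), whose sequence is shared with other H4 genes. Without Lv_NC library 1, IFT80 was at 0 counts in Lv_NC and the log2 fold changes of CEP162 and ARHGAP28 were 3.55 and 3.83. That of IFT80 was 5.28 without Lv_NC library 2, that of WNT2B 1.73 without Lv_LINC00673 library 1 and that of LOC105379271 2.20 without Lv_LINC00673 library 2. Calls were lost for IFT80 without Lv_LINC00673 library 2 (adjusted p = 0.0526) and for MFSD2B without Lv_NC library 1, 2 or 3 (0.0822, 0.106 and 0.0521). Without Lv_LINC00673 library 2 or 3 or Lv_NC library 3 they were lost for LOC105379271 (0.0808, 0.054 and 0.0689), ARHGAP28 (0.088, 0.0641 and 0.0939) and POTEJ (0.0526, 0.0554 and 0.0566). With the offset CEP162, ARHGAP28, TTN and SHOC1 had smaller log2 fold changes of 2.27, 2.02, 1.62 and 1.57.

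Among the lowest fold changes were cytokine and acute-phase genes. The interleukin gene IL24 fell from 9.79 ± 0.768 to 2.11 ± 0.315 CPM (log2 fold change -2.22, SE 0.18, adjusted p = 0.00105). The chemokine genes CCL3L1, CCL3 and CCL3L3, at the last 2 of these on numbered copy rows, had log2 fold changes of -2.76, -2.26 and -2.01, and the acute-phase gene SAA1 one of -2.40. The CCL3L3 row without a copy number did not pass (-1.61, SE 0.55, adjusted p = 0.059), while that of CCL3 did (-2.20, adjusted p = 0.0032). CCL3L1 stood at 4.63, 12.6 and 4.22 CPM in the Lv_NC libraries, and its log2 fold change was -2.07 without Lv_NC library 2. That of SAA1 was -1.80 without Lv_NC library 1. These are members of families of near-identical genes and are uncertain, as are a copy row of the lncRNA GIHCG (-2.86) and the lncRNA LOC102723393 (-1.98). The mitochondrial row TRNC, at positions 5761 to 5826 of the mitochondrial genome, had 2 counts in each Lv_LINC00673 library and 3124, 3922 and 3043 in Lv_NC. From the summed counts of 6 and 10089 the ratio of Lv_NC to Lv_LINC00673 was 1514 (95% exact interval 695 to 4127, counting error only). The neighbouring tRNA rows TRNY and TRNN had 3809 to 5570 and 4689 to 6571 counts per library, and whether TRNC was counted in the same way in both groups is not given in the sources used here, so this ratio is uncertain.

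Heat shock and immediate early genes fell as a list. Of 20 tested, 11 fell and 2 rose (13 and 2 adjusted over the list alone), with a median log2 fold change of -0.53. The inducible HSP70 genes HSPA1A and HSPA1B fell from 176 ± 15.9 to 57.6 ± 8.93 CPM and from 150 ± 10.5 to 48.4 ± 5.56 CPM. Their sequences are nearly identical and each has further numbered copies, so they are uncertain one by one, and with copies summed their log2 fold changes were -1.61 and -1.64. The orphan receptor gene NR4A1 fell from 152 ± 13.3 to 62.9 ± 6.19 CPM. HSPH1, a co-chaperone gene, rose from 20.2 ± 4.70 to 52.0 ± 10.3 CPM, and the chaperone gene HSP90AA1 from 109 ± 19.5 to 259 ± 51.3 CPM. HSPA8, HSPB1 and BAG3 did not pass. The camera test gave an adjusted p of 5.76e-05 (adjusted p = 0.164 with an estimated correlation). Of the 20 genes, 10 fell and 3 rose in the offset values, with a median of -0.27. The 3 were HSPH1, HSP90AA1 and HSPB1, at log2 fold changes of 0.82, 1.15 and 0.29. The only heat shock genes still lower were HSPA1A, HSPA1B and DNAJB1. In fry the list passed (adjusted p = 0.0016), but in fry with a replicate block it did not (adjusted p = 0.0518).

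Genes of the amino acid stress and oxidative stress lists also fell. Of 24 ATF4 and amino acid stress genes tested, 16 fell and 2 rose (18 and 2 adjusted over the list alone; median log2 fold change -0.55, camera adjusted p = 1.05e-05, adjusted p = 0.153 with an estimated correlation). PPP1R15A, which encodes a regulator of eIF2 alpha dephosphorylation, fell from 550 ± 49.0 to 217 ± 19.3 CPM, the transcription factor genes DDIT3 and ATF3 from 47.1 ± 14 to 24.0 ± 2.69 and from 41.5 ± 4.82 to 21.7 ± 2.20 CPM. The folate enzyme gene ALDH1L2 rose from 3.01 ± 0.401 to 6.61 ± 1.48 CPM. Of 21 oxidative stress genes, 16 fell and 0 rose (16 and 0 adjusted over the list alone; median -0.71, camera adjusted p = 1.61e-07, adjusted p = 0.153 with an estimated correlation). The metallothionein gene MT1X fell from 135 ± 30.5 to 52.8 ± 2.49 CPM, the haem oxygenase gene HMOX1 from 98.1 ± 8.27 to 39.1 ± 7.41 CPM, the ferritin light chain gene FTL from 2297 ± 179 to 1208 ± 87.3 CPM and OSGIN1 from 54.2 ± 5.14 to 29.2 ± 5.62 CPM. MT1X and FTL have close relatives or pseudogenes and are uncertain. In the offset values, 15 of the first list fell and 1 rose, and 14 of the second fell, with a median of -0.43 for each list. The log2 fold change of ALDH1L2 went from 1.13 to 0.54 with the offset. With library totals alone the lower counts were 11 and 14. DDIT3 lost its call with the offset (log2 fold change -0.60, adjusted p = 0.0749) and without Lv_LINC00673 library 2 (adjusted p = 0.053).

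NF-kappaB and inflammatory genes fell as a list. Of 22 tested, 10 fell and 0 rose (10 and 0 adjusted over the list alone; median log2 fold change -0.36, camera adjusted p = 0.000149, adjusted p = 0.153 with an estimated correlation). The chemokine gene CCL20 fell from 33.4 ± 2.86 to 13.5 ± 1.13 CPM, CSF2, encoding a growth factor of granulocytes and macrophages, from 19.1 ± 0.622 to 8.37 ± 1.02 CPM, the NF-kappaB inhibitor gene NFKBIA from 134 ± 9.39 to 65.4 ± 5.28 CPM and CXCL8, encoding interleukin 8, from 48.2 ± 6.25 to 24.4 ± 3.62 CPM. In the offset values, as with library totals alone, 8 of the 22 fell and 0 rose, and the offset median was -0.35.

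Interferon-stimulated genes rose as a list. Of 32 tested, 12 rose and 1 fell (13 and 1 adjusted over the list alone), with a median log2 fold change of 0.56. HERC6 rose from 1.39 ± 0.409 to 6.01 ± 1.71 CPM, SAMD9 from 2.55 ± 0.930 to 8.52 ± 2.31 CPM, the antiviral gene IFIT2 from 3.70 ± 0.852 to 11.8 ± 2.41 CPM and the helicase gene DDX60 from 5.70 ± 1.72 to 17 ± 3.79 CPM. The camera adjusted p was 0.00954 (adjusted p = 0.447 with an estimated correlation). In the offset values 12 rose and 0 fell, with a median of 0.50, and SAMD9 and DDX60 went from log2 fold changes of 1.74 and 1.58 to 1.00 and 0.93. In fry the list passed (adjusted p = 0.0176), but in fry with a replicate block it did not (adjusted p = 0.0901). With library totals alone 14 rose and 0 fell.

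Replication-dependent histone genes, whose messages normally lack a poly(A) tail, rose as a list. Of 18 tested, 9 rose and 0 fell (9 and 0 adjusted over the list alone), with a median log2 fold change of 0.82. H2AC6 rose as given above, H4C14 from 14.6 ± 1.41 to 31.2 ± 2.10 CPM and H2BC4 from 9.20 ± 0.433 to 19.3 ± 0.954 CPM. H4C3 had 80 counts over 3 libraries against 22. Histone genes of a class share sequence, so single members are uncertain. The camera adjusted p was 0.000236 (adjusted p = 0.153 with an estimated correlation), and 13 rose and 0 fell in the offset values, with a median of 1.17. With library totals alone 11 rose and 0 fell. H4C3 lost its call whichever library was left out (adjusted p = 0.122, 0.134 and 0.122 without Lv_LINC00673 libraries 1 to 3, and 0.106, 0.131 and 0.0531 without Lv_NC libraries 1 to 3), with a log2 fold change of 2.57 without Lv_NC library 3 against 1.98 with all libraries.

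Genes of ribosomes, respiration, lysosomes and cholesterol synthesis fell by smaller amounts. Of 75 cytosolic ribosomal protein genes, 42 fell and 1 rose (51 and 2 adjusted over the list alone; median log2 fold change -0.35, camera adjusted p = 9.93e-10, adjusted p = 0.153 with an estimated correlation). RPS27 fell from 487 ± 48.9 to 305 ± 10.6 CPM and RPL15 from 1484 ± 79.3 to 1018 ± 97.8 CPM. RPL7 rose from 278 ± 41.3 to 426 ± 72.4 CPM. Ribosomal protein genes have many processed pseudogenes and are uncertain one by one. Of 33 nuclear-encoded respiratory chain genes, 23 fell and 0 rose (25 and 1 adjusted over the list alone; median -0.44, camera adjusted p = 1.49e-07, adjusted p = 0.229 with an estimated correlation). SDHB, a subunit of succinate dehydrogenase, fell from 164 ± 12.9 to 102 ± 3.85 CPM. Of 28 lysosome and autophagy genes, 10 fell and 1 rose (10 and 1 adjusted over the list alone; median -0.27, camera adjusted p = 0.000867, adjusted p = 0.220 with an estimated correlation). The cathepsin gene CTSL fell from 161 ± 1.71 to 98.5 ± 2.69 CPM. Of 23 cholesterol synthesis genes, 9 fell and 1 rose (9 and 1 adjusted over the list alone; median -0.17, camera adjusted p = 0.018, adjusted p = 0.216 with an estimated correlation). INSIG1, encoding a regulator of sterol synthesis, fell from 16.6 ± 1.32 to 11.1 ± 0.233 CPM. In the offset values the ribosomal list had 20 lower, 2 higher and a median of -0.02, the respiratory list 9 lower, 0 higher and -0.13, the lysosome list 9 lower, 2 higher, a median of -0.16 and a camera adjusted p of 0.0541, and the cholesterol list 4 lower, 2 higher and -0.15. With library totals alone 19 ribosomal genes fell and 2 rose (median -0.19), 13 respiratory genes fell and 1 rose (-0.28), 7 lysosome genes fell and 1 rose (-0.11), and 5 cholesterol genes fell and 1 rose (-0.0070). The cholesterol call was lost without Lv_LINC00673 library 1 (adjusted p = 0.118), with a filter of at least 1 CPM in 3 libraries (0.0751), on log2(FPKM + 1) (0.173) and in fry with a replicate block (0.121). Without Lv_LINC00673 library 2 or 3 or Lv_NC library 3 the calls of RPL7 (adjusted p of 0.0635, 0.0575 and 0.061) and INSIG1 (0.052, 0.0563 and 0.061) were lost.

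**Figure D3:**
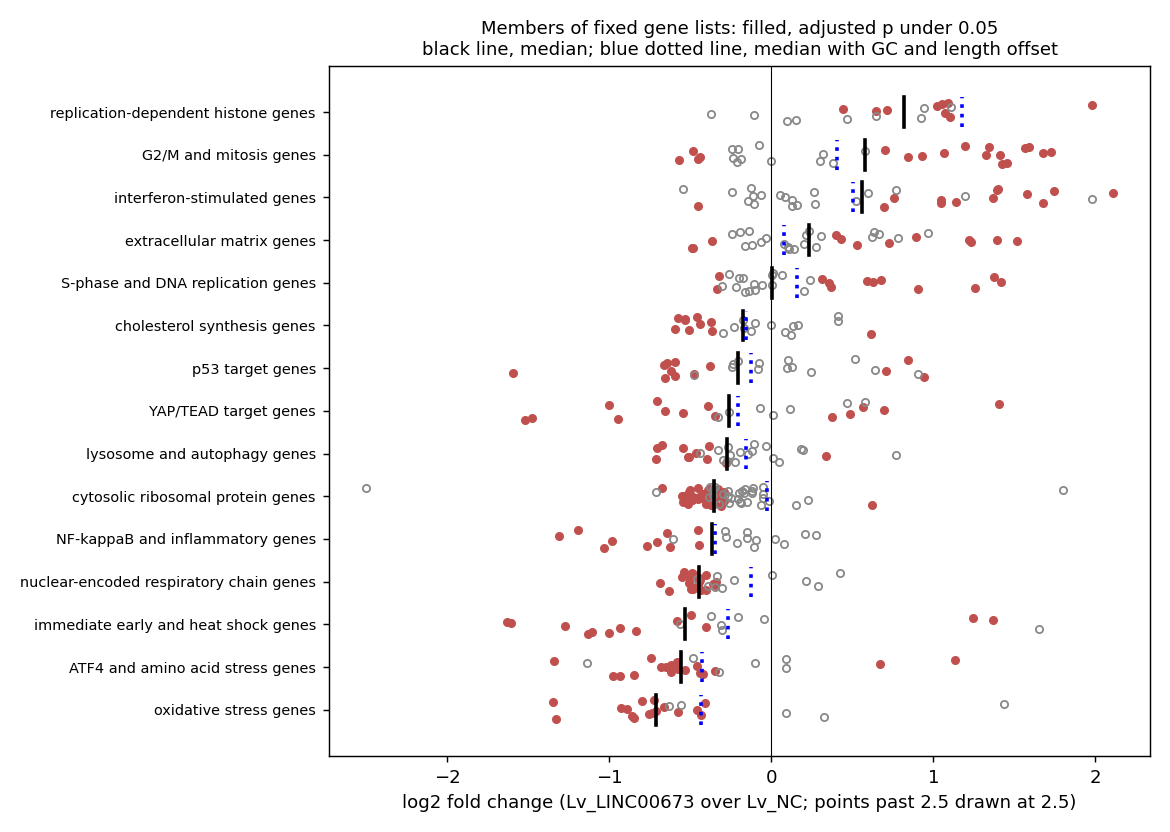
Log2 fold change (Lv_LINC00673 over Lv_NC) of the tested members of 15 gene lists, filled where the edgeR adjusted p was under 0.05, with the list median (black line) and the median with the GC and length offset (blue dotted line). Points beyond 2.5 in size are drawn at 2.5. The median was -0.71 for oxidative stress genes and 0.82 for replication-dependent histone genes.

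Cell cycle genes included many that rose, but neither list passed the camera test. Of 29 G2/M and mitosis genes, 14 rose and 4 fell (15 and 5 adjusted over the list alone; median log2 fold change 0.58, camera adjusted p = 0.1004). Those that rose included the centromere genes CENPF, from 17.1 ± 5.49 to 56.5 ± 14.3 CPM, and CENPE, from 6.35 ± 1.15 to 20.3 ± 6.04 CPM, and the spindle genes ASPM, from 4.36 ± 1.92 to 13.1 ± 3.79 CPM, and HMMR, from 6.14 ± 2.31 to 18.2 ± 5.02 CPM. Of 28 S-phase and DNA replication genes, 10 rose and 2 fell (11 and 3 adjusted over the list alone; median 0.01, turning to -0.02 with RLE and -0.0036 with upper-quartile factors, camera adjusted p = 0.707). Those that rose included the polymerase gene POLA1, from 5.12 ± 1.53 to 13.7 ± 2.24 CPM, and CCNE2, encoding cyclin E2, from 1.96 ± 0.548 to 5.09 ± 1.56 CPM. With the GC and length offset both passed, at camera adjusted p of 0.0112 and 0.0486 (adjusted p = 0.681 and 0.545 with an estimated correlation). The G2/M list also passed without Lv_NC library 1 (camera adjusted p = 0.0431) and on log2(FPKM + 1) (0.0252). With the offset 15 G2/M genes rose and 1 fell (median 0.41), and 11 S-phase genes rose and 2 fell (median 0.16). The log2 fold changes of CENPF, CENPE and ASPM went from 1.73, 1.68 and 1.59 to 0.93, 0.80 and 0.69. Without Lv_NC library 3 the calls of ASPM and CCNE2 were lost (adjusted p = 0.0512 and 0.054).

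Targets of p53, YAP and ERK signalling moved both ways. Of 25 p53 target genes, 9 fell and 3 rose (11 and 4 adjusted over the list alone; camera adjusted p = 0.1004): the cytokine gene GDF15 fell from 27.0 ± 2.49 to 8.96 ± 1.89 CPM and MDM2, encoding the ubiquitin ligase of p53, rose from 29 ± 6.35 to 55.7 ± 11.5 CPM. Of 21 YAP/TEAD target genes, 9 fell and 5 rose (9 and 6 adjusted over the list alone; camera adjusted p = 0.136, 0.00179 with the offset, 0.396 with the offset and an estimated correlation), including CCN1 as above, ANKRD1, which fell from 454 ± 54.9 to 163 ± 30.6 CPM, and MYOF, which rose from 9.79 ± 2.78 to 26.0 ± 6.62 CPM. Of 17 ERK output genes, 7 fell and 2 rose (7 and 2 adjusted over the list alone; camera adjusted p = 0.223), including the transcription factor gene MYC, which fell from 669 ± 64.7 to 333 ± 31.7 CPM, and ETV1, which rose from 1.26 ± 0.239 to 3.87 ± 0.112 CPM. Of 23 apoptosis regulators, 6 fell and 2 rose (7 and 2 adjusted over the list alone; camera adjusted p = 0.299), among them HRK, which fell from 16.6 ± 0.546 to 8.76 ± 0.861 CPM, and BIRC2, which rose from 13.4 ± 4.50 to 28.8 ± 6.62 CPM. With the offset 8 p53 genes fell and 2 rose, 7 YAP/TEAD genes fell and 2 rose, 6 ERK genes fell and 2 rose, and 8 apoptosis genes fell and 2 rose. Library totals alone gave 7 lower p53 genes, 5 lower YAP/TEAD genes and 5 lower ERK genes. MDM2 lost its call with the offset (log2 fold change 0.94 to 0.29, adjusted p = 0.0867), and ETV1 went from 1.62 to 0.95. BIRC2 lost its call without Lv_LINC00673 library 2 or 3 or Lv_NC library 3 (adjusted p = 0.0686, 0.0562 and 0.0625), and the ERK list passed on log2(FPKM + 1) (camera adjusted p = 0.0347).

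Matrix and differentiation lists did not pass the camera test on the counts, with changes among single members. On log2(FPKM + 1) the extracellular matrix list passed, at a camera adjusted p of 0.0254. Of 33 extracellular matrix genes, 9 rose and 3 fell (10 and 3 adjusted over the list alone; camera adjusted p = 0.149), including fibronectin, FN1, from 321 ± 57.1 to 920 ± 175 CPM, and fibrillin 1, FBN1, from 4.88 ± 1.77 to 12.8 ± 3.41 CPM. Of 26 matrix proteases and inhibitors, 6 fell and 4 rose (6 and 4 adjusted over the list alone; camera adjusted p = 0.486), with stromelysin MMP3 falling from 408 ± 24.3 to 214 ± 17.9 CPM and collagenase MMP1 rising from 3.24 ± 0.787 to 6.65 ± 1.27 CPM. Of 24 epithelial-mesenchymal transition regulators and adhesion genes, 7 rose and 6 fell (7 and 7 adjusted over the list alone; camera adjusted p = 0.961), with the repressor gene ZEB1 rising from 3.80 ± 1.52 to 8.57 ± 1.72 CPM. Of 13 osteoblast and bone genes, 3 rose and 3 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.807), with RUNX2, the master regulator of osteoblasts, rising from 1.83 ± 0.138 to 4.35 ± 1.25 CPM and BMP2 falling from 44.7 ± 1.74 to 25.3 ± 1.13 CPM. Of 14 chondrocyte genes, 2 rose and 0 fell (1 and 0 adjusted over the list alone; median 0.42, also 0.42 with COL10A1 at its bound; camera adjusted p = 0.542). They were SOX5, from 0.969 ± 0.253 to 2.02 ± 0.590 CPM, and COL10A1, with counts of 10, 20 and 20 against 0 in each Lv_NC library, at least 18.5-fold higher when 3 counts are set over the Lv_NC group. After the offset, 9 matrix genes rose and 3 fell, 3 protease genes rose and 5 fell, 3 epithelial-mesenchymal transition genes rose and 3 fell, 4 bone genes rose and 4 fell, and 1 chondrocyte gene rose and 1 fell (median 0.24). The log2 fold change of FN1 went from 1.52 to 0.88. Library totals alone gave 14 higher matrix genes and 3 lower epithelial-mesenchymal transition genes. ZEB1 and SOX5 lost their calls with the offset, going from 1.17 to 0.55 (adjusted p = 0.0706) and from 1.06 to 0.14 (adjusted p = 0.727). Calls were also lost for ZEB1 without Lv_LINC00673 library 2 or Lv_NC library 3 (adjusted p = 0.0746 and 0.0788) and for MMP1 without Lv_LINC00673 library 3 or Lv_NC library 3 (0.0574 and 0.0563). They were lost for COL10A1 without Lv_LINC00673 library 2 or 3 (0.0597 and 0.0586), and for SOX5 without Lv_LINC00673 library 2 or 3 or Lv_NC library 2 or 3 (0.135, 0.0525, 0.0864 and 0.109).

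Of 22 TGF-beta target genes, 3 rose and 3 fell (3 and 5 adjusted over the list alone; camera adjusted p = 0.751), among them TGFBR1, from 9.93 ± 2.18 to 23.6 ± 5.92 CPM, and BAMBI, from 12.2 ± 0.743 to 6.16 ± 1.84 CPM. Of 14 Wnt target genes, 3 rose and 2 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.707), with RNF43 rising from 3.19 ± 0.381 to 5.67 ± 0.341 CPM and TNFRSF19 having counts of 12, 12 and 28 against 0, 0 and 4 (14.4-fold, 95% exact interval 5.31 to 55.0, counting error only). The offset values had 4 TGF-beta genes higher and 3 lower, and 3 Wnt genes higher and 1 lower, and TGFBR1 went from a log2 fold change of 1.25 to 0.57. TNFRSF19 lost its call with the offset (adjusted p = 0.0529) and without Lv_LINC00673 library 1, 2 or 3 or Lv_NC library 1 or 2 (adjusted p = 0.0775, 0.112, 0.195, 0.107 and 0.132), and was at 0 counts in Lv_NC without Lv_NC library 3. BAMBI lost its call without Lv_NC library 3 (adjusted p = 0.0523).

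Metabolic lists were also mixed. Of 21 hypoxia genes, 6 rose and 6 fell (6 and 6 adjusted over the list alone; camera adjusted p = 0.961), with CA9 as above and the histone demethylase gene KDM3A rising from 10.8 ± 1.82 to 22.8 ± 4.41 CPM. Of 21 glycolysis genes, 5 fell and 0 rose (5 and 0 adjusted over the list alone; camera adjusted p = 0.397), with phosphofructokinase PFKM falling from 195 ± 16.7 to 124 ± 7.04 CPM, while 10 rose and 3 fell in the offset values. Of 18 fatty acid synthesis and desaturation genes, 3 rose and 2 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.883), with the elongase gene ELOVL6 rising from 10.7 ± 1.66 to 22 ± 4.28 CPM. Of 18 unfolded protein response genes, 4 rose and 2 fell (5 and 5 adjusted over the list alone; camera adjusted p = 0.883), with the endoplasmic reticulum chaperone genes HSP90B1 rising from 101 ± 28.6 to 294 ± 51.7 CPM and HSPA5 from 796 ± 54.1 to 1233 ± 107 CPM. The median, mean and test of a list differed in sign for the fatty acid, unfolded protein response, matrix protease, TGF-beta, LINC00673-tied, neighbour, epithelial and housekeeping lists, and the median of glycolysis, protease, TGF-beta, fatty acid, unfolded protein response, apoptosis, LINC00673-tied, neighbour and housekeeping lists turned positive with library totals alone. After the offset, 7 hypoxia genes rose and 4 fell, 3 fatty acid genes rose and 5 fell, and 7 unfolded protein response genes rose and 2 fell. The log2 fold change of ELOVL6 went from 1.04 to 0.44.

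Other RNA classes and markers of other cell types gave single changes. Of 16 nuclear noncoding RNAs, 6 rose and 3 fell (6 and 3 adjusted over the list alone; camera adjusted p = 0.295), with MALAT1 rising from 35.4 ± 12.3 to 118 ± 42.0 CPM and MIAT falling from 1.28 ± 0.261 to 0.261 ± 0.221 CPM. Of 14 genes tied to LINC00673 in other tumour types, 5 rose and 4 fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.751), including PTPN11, encoding the phosphatase SHP2, from 54.2 ± 15.8 to 94.6 ± 20.4 CPM. Of 18 housekeeping genes, 7 fell and 3 rose (7 and 3 adjusted over the list alone; camera adjusted p = 0.450), with beta-actin, ACTB, at a log2 fold change of -0.52 (-0.36 with library totals alone). Among blood and immune markers 1 of 10 rose and 0 fell (0 and 0 adjusted over the list alone), among endothelial markers 1 of 9 rose and 0 fell (1 and 0 adjusted over the list alone), among epithelial markers 1 of 13 rose and 3 fell (1 and 3 adjusted over the list alone), and among neural and muscle markers 2 of 14 rose and 1 fell (2 and 1 adjusted over the list alone), with camera adjusted p of 0.542, 0.383, 0.751 and 0.397. The single genes of the first 2 were ITGAM, at 1.10 ± 0.0666 against 0.368 ± 0.229 CPM, and TIE1, at 11.8 ± 0.386 against 7.17 ± 1.62 CPM. The list of mitochondrially encoded protein genes had 0 members under its gene names and was not analysed here. With the offset 4 noncoding RNAs rose and 4 fell, 2 LINC00673-tied genes rose and 2 fell, 4 housekeeping genes rose and 4 fell, 3 blood markers rose and 0 fell, 1 endothelial marker rose and 0 fell, 3 epithelial markers rose and 2 fell, and 4 neural and muscle markers rose and 0 fell. The log2 fold change of MALAT1 went from 1.74 to 0.98 with the offset. PTPN11 lost its call with the offset (0.80 to 0.31, adjusted p = 0.134) and without Lv_LINC00673 library 2 or 3 or Lv_NC library 2 or 3 (0.103, 0.0777, 0.0678 and 0.101). Calls were lost for MALAT1 without Lv_LINC00673 library 2 (adjusted p = 0.054) and for MIAT without Lv_NC library 3 (0.0559), and the log2 fold change of MIAT went from -2.29 to -3.24 without Lv_LINC00673 library 3. ITGAM lost its call without Lv_LINC00673 library 1, 2 or 3 or Lv_NC library 1 or 3 (adjusted p = 0.0933, 0.122, 0.107, 0.0626 and 0.0559), and TIE1 without Lv_LINC00673 library 1, 2 or 3 or Lv_NC library 3 (0.0509, 0.0702, 0.0743 and 0.0787).

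Genes beside LINC00673 passed the test about as often as genes elsewhere. Of 19 genes tested within 2 Mb, 5 passed (26.3%, against 26.8% of the other tested genes; Fisher's exact test, two-sided, p = 1). C17orf80, from 73232433 to 73248959 on chromosome 17, rose from 10.1 ± 1.27 to 19.0 ± 1.79 CPM. SLC39A11, encoding a zinc transporter, SDK2, encoding a cell adhesion protein, RPL38 and CDC42EP4 fell, with log2 fold changes of -0.59, -0.45, -0.36 and -0.33. With the offset RPL38 and CDC42EP4 were at -0.00067 and -0.08 and lost their calls (adjusted p = 0.996 and 0.408). SSTR2 and COG1 gained calls with it, at -0.76 and 0.34 (adjusted p = 0.0332 and 0.0234). Of the 19 genes 5 again passed, 2 higher and 3 lower. Leaving out any library but Lv_LINC00673 library 1 ended the call of CDC42EP4 (adjusted p = 0.139 and 0.131 without Lv_LINC00673 libraries 2 and 3, and 0.0743, 0.149 and 0.0718 without Lv_NC libraries 1 to 3). That of SDK2 ended without Lv_LINC00673 library 2 or 3 or Lv_NC library 2 or 3 (adjusted p = 0.0578, 0.0602, 0.0514 and 0.0584). SOX9, the chondrocyte transcription factor gene at 72121020 to 72126416, had a log2 fold change of -0.13 (SE 0.10, adjusted p = 0.386). On the fixed list of 13 tested neighbours, 3 fell and 1 rose (3 and 2 adjusted over the list alone; camera adjusted p = 0.543). With the offset 3 neighbours on it fell and 2 rose.

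Whole chromosomes shifted by small amounts. Chromosomes 13, 4, 5 and 2 had the highest median log2 fold changes, at 0.30, 0.26, 0.23 and 0.21, and chromosome 19 the lowest, at -0.14, where random gene sets matched on expression spanned -0.05 to 0.02 for chromosome 19. For these 5 the p was 0.0002, the smallest that 10000 random sets can give, and 11 of 23 chromosomes passed an adjusted p of 0.05. Median transcript GC content was 43.2, 42.9, 44.8 and 46.2% on chromosomes 13, 4, 5 and 2 and 58.6% on chromosome 19. With the GC and length offset 7 chromosomes passed, and chromosomes 4, 6 and 19 passed in the opposite direction. Chromosome 4 had a median of 0.05, below its random sets (0.07 to 0.16). Chromosome 6 had one of 0.07, below its sets (0.09 to 0.16), after 0.16, above them (0.04 to 0.15), without the offset. Chromosome 19 had one of 0.11, above its random sets (0.04 to 0.09). Chromosome 2 stayed above its sets, at 0.14 (0.05 to 0.11). Chromosome 18 passed only with the offset, at -0.03, below its sets (0.04 to 0.18; adjusted p = 0.0023), after 0.17 without it. Chromosomes 16 and 22 also passed only with the offset, at 0.11 and 0.10, above their sets (adjusted p = 0.0103 and 0.0289). Chromosomes 13 and 5 no longer passed, at 0.08 (adjusted p = 0.104) and 0.10 (adjusted p = 0.960).

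The groups parted along the first principal component, which held 46.0% of the variance of the tested genes. Lv_LINC00673 libraries lay at -32.7, -71.3 and -54.3 and Lv_NC libraries at 28.4, 74.5 and 55.4. Pearson correlations between libraries, across genes, were 0.974 to 0.977 within groups and 0.949 to 0.971 between groups. Within a group no pair of libraries agreed within sampling noise. Ribosomal RNA made up 1.83, 1.91 and 2.38% of counts in Lv_LINC00673 and 1.92, 1.45 and 1.26% in Lv_NC.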

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

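The GC and length offset, its forms, summed copies, thinning and the fit without the first libraries were chosen after the data were seen. The count of 5883 genes, 1837 by at least 2-fold, was 5275 to 6829 in the fits that changed the tool, scaling factors, count filter or robust setting, but the lower count fell to 1224 with library totals alone. With a replicate block the counts were 1208 in all, 778 by 2-fold, 800 higher and 408 lower. Equal replicate numbers do not pair the libraries (correlations of deviations -0.12, -0.11 and 0.00, and 0 of 6 libraries correlated best with their own number). On FPKM values, log2(FPKM + 1) gave 478 by 2-fold and 1369 lower, log2(FPKM + 0.1) 1351 lower, and log2(FPKM + 1) with no filter 1536 in all, 344 by 2-fold, 1140 higher and 396 lower. The GC and length offset gave 744 by 2-fold, and with the replicate block 2987 in all, 527 by 2-fold, 1557 higher and 1430 lower. Leaving out 1 library gave 2716 to 6490 in all, 945 to 2322 by 2-fold, 1453 to 3254 higher and 1172 to 3269 lower. Thinning gave 5900, summed copies 6073 and leaving out the first libraries 6965.

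LINC00673 passed the threshold in 0 of 24 alternatives, with adjusted p of 0.0528 to 0.714. Of 155 other genes chosen by the rule, 39 lost their call without Lv_LINC00673 library 2, 38 without library 3, 39 without Lv_NC library 3, 19 without Lv_NC library 2, 27 besides ACSL3 with the offset, 74 with the replicate block, 53 besides ACSL3 with both and 77 on log2(FPKM + 1) with no filter. Without library 1 of Lv_LINC00673 or of Lv_NC 6 and 8 lost it. ACSL3 lost its call and changed sign with the offset, to -0.021 (-0.019 with the block too; adjusted p = 0.899 and 0.922). The 10 list calls became 0 with an estimated correlation and 9 to 11 when a library was left out. On log2(FPKM + 1) 12 lists passed, 9 of the 10 and the G2/M, ERK output and extracellular matrix lists. The first principal component held 35.6% over 500 variable genes, and 7 chromosomes passed with the offset. Within 5 Mb of LINC00673, 36 of 118 tested genes passed (30.5%, against 26.8% of the other tested genes). Where no cause is given above, the cause was not tested. On the FPKM filter 32 of the 35 lists could be tested, since the others had fewer than 5 members.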

Other observations

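Counts in further gene families, chosen after the data were seen and not tested as sets, were as follows. Of 78 genes for mitochondrial ribosomal proteins 42 fell and 0 rose, with a median log2 fold change of -0.36, and of 36 proteasome genes 19 fell and 3 rose (median -0.36). With the offset these were 24 lower and 1 higher, and 10 lower and 2 higher, with medians of -0.12 and -0.13. Library totals alone gave medians of -0.19 and -0.20, and -0.15 for the keratin genes below. Of 469 zinc finger genes named ZNF, 144 rose and 25 fell (median 0.48), and 96 rose and 28 fell with the offset (median 0.26). Of 15 chemokine genes 6 fell and 0 rose (5 and 1 with the offset). Of 22 keratin genes 9 fell and 0 rose, but 5 fell and 2 rose with the offset, where the median turned from -0.31 to 0.01. The metal-responsive genes MT2A, MT1E and MT1X, close relatives and so uncertain one by one, fell, with log2 fold changes of -0.79, -0.73 and -1.35 (-0.31, -0.24 and -0.87 with the offset, where MT1E lost its call at an adjusted p of 0.0677). The zinc exporter gene SLC30A1 fell from 75.9 ± 1.41 to 38.3 ± 3.04 CPM (log2 fold change -0.98, and -1.655 with the offset). Mitochondrial tRNA rows beside TRNC did not pass the threshold, with log2 fold changes of 0.22 for TRNY (SE 0.14, adjusted p = 0.276) and 0.21 for TRNN (SE 0.13, adjusted p = 0.257). Of 1019 tested rows without a symbol, 84 rose and 69 fell. The 5883 calls came from the real grouping, while the highest of the other splits gave 1 (1 of 10 splits as large), and 10 splits are too few for a share under 0.05.

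In this and the following paragraphs, all tests but that of the label of Lv_NC library 3 were chosen after the results were seen. Fold changes rose with gene length and fell with GC content. A difference in library size is argued against: with every library thinned to the smallest total the correlation with length was 0.48, as before. A bias between library preparations may account for the trend, and no value here excludes it: slopes per doubling of length were 0.08, 0.14 and 0.09 in Lv_LINC00673 and -0.08, -0.14 and -0.10 in Lv_NC, a gap of 0.16 that follows the groups, so preparation and group cannot be told apart. Slopes per 10 points of GC content were 0.03, -0.25 and -0.18 in Lv_LINC00673 and 0.01, 0.28 and 0.11 in Lv_NC, so those of the first libraries did not part the groups. Both kinds of slope are of each library's deviation from the gene mean over all 6 libraries. Only differences between libraries can be read from them, not their signs. A biological effect of the vector on long, AT-rich transcripts is likewise open and was not tested.

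Of the 20 heat shock and immediate early genes tested, 11 were lower in Lv_LINC00673 and 2, HSPH1 and HSP90AA1, were higher. The GC and length trend as the whole cause is argued against for 9 of the 11 lower members, which stayed lower with the offset, while HSPE1 and IER2 went from -0.50 (SE 0.09) to -0.07 (SE 0.08) and from -0.40 (SE 0.10) to -0.02 (SE 0.06) and lost their calls because the fold shrank. A shift of reads to numbered copies is argued against for HSPA1A and HSPA1B, the 2 of the 11 with such copies. The copy rows HSPA1A-3 and HSPA1B-2 were lower too, at log2 fold changes of -1.58 and -1.66. With copies summed 2 of 2 stayed lower, which adds little, since these rows moved alike. Summing does not separate reads shared between HSPA1A and HSPA1B. Reads shared with other relatives were not tested. Differences in handling or harvest between the groups, an effect of the vector if Lv_NC had none, and an effect of LINC00673 depletion, may each underlie the pattern and were not tested.

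LINC00673 did not pass the threshold in libraries made to study its depletion. Too few reads are argued against as the reason for not seeing a fall by 2-fold, since the lower bound of its level was 58.1% of Lv_NC. A wrong label on Lv_NC library 3 as a finished library, whose LINC00673 count was lowest in its group, is argued against: at 92.0% of the 2907 genes called without that library and also tested with it, it lay nearer the other Lv_NC libraries. Since preparation and group cannot be told apart, this does not cover a mix-up of cells before the libraries were prepared. A weak depletion at the time of harvest, or one of transcript forms that the gene-level count does not separate, may remain as candidate explanations and were not tested. With the GC and length offset its log2 fold change was -0.10 (SE 0.15), so these libraries do not establish that LINC00673 was depleted at all.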
